A study of Mus musculus with 4 samples.

How the data were processed

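Small RNA libraries were made from total RNA of whole testes of 16-day-old mice, 2 of wild-type animals and 2 of animals with a knockdown of Hsf5, per the labels. Adaptors were ligated to both RNA ends, and inserts of 18 to 40 bases were selected, per the labels' protocol. The deposited table names the knockdown libraries as knockouts, and the wording of the labels was followed here. Cutadapt, an adaptor trimmer, and the genome build mm39 are named in the submitters' processing notes, with no role or order. The aligner, the mismatches allowed and the order of the annotation classes are not given in the sources used here.

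The deposited table gave 1 line for each distinct sequence, library and annotation, with raw read counts made by the authors and not normalized. Another column held a ratio, the authors' scaling factor, which equalled in each library 1000000 divided by the reads of mature miRNAs (0.499, 0.716, 0.512 and 0.539 in wild type replicates 1 and 2 and knockdown replicates 1 and 2). The factor was used only as an alternative scaling. The table had 12700077 lines for 6208912 pairs of sequence and library, with lengths of 16 to 47 nt. Of these pairs, 927801 stood on more than 1 line, nearly all as gene annotations, and always with the same count. Each pair was therefore counted once, which removed 6491165 repeated lines. Without that step a read in a gene with several transcripts would be counted several times.

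The authors' names for a sequence differed between libraries. This held for 33.2% of piRNA cluster sequences found in at least 2 libraries, 23.6% of LINE, 19.0% of SINE, 13.3% of LTR and 2.96% of miRNA sequences. By reads of such sequences it held for 56.3%, 33.6%, 57.9%, 23.5% and 3.07%, in the same order. The class itself differed for 19.7% of these LINE reads, 35.1% of SINE reads and 11.3% of LTR reads. To keep such choices from making differences, each of the 4496542 distinct sequences was given 1 name and class over all libraries, and the names as deposited were an alternative. The shares of LINE, LINE1, SINE and LTR reads below rest on the class given in this way. Names of piRNA transcripts were summed into 214 loci, 114 named after a gene and 100 by chromosome band. Sequences were matched to GRCm39, the Ensembl name of the build mm39, and annotated with GENCODE M39. All loci lay where the table put them, and 99.6% of their reads with 1 place in the genome lay on the main strand of the locus. Of the 25 to 31 nt reads, 87.7%, 88.0%, 88.2% and 88.6% matched the genome exactly. Full-length LINE1 elements were found in GRCm39 by an intact second open reading frame. The ping-pong overlap was the Z score of 10 nt overlaps of 5' ends of opposite strands against overlaps of 1 to 9 and 11 to 20 nt.

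Total counts were 11117460, 9260452, 9619666 and 10900306 reads, and at this depth a count of 0 allows up to 0.324 RPM in the shallowest library. Counts over the miRNAs of libraries of 1 group differed beyond sampling noise, with a chi-square per degree of freedom of 29.5 in the wild type and 408 in the knockdown, so neither group held copies of 1 library. Pairs across the groups were not compared in this way. Each group had 2 libraries. Shares were taken of reads of 18 to 40 nt, and compared by an exact two-sided permutation test over the 6 assignments.

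Counts per sequence, per miRNA (reads of 18 to 25 nt, mature and hairpin names apart), per piRNA locus (25 to 31 nt) and per transposon family were tested with edgeR's quasi-likelihood F test (robust, TMM factors) with Benjamini-Hochberg adjustment at 0.05. Features needed 1 CPM in at least 2 libraries. The transposon family test was added after the table was seen. TMM factors over the loci were 0.661 in knockdown replicate 1 and 1.12, 1.14 and 1.19 in the others, so scaling raised the kept loci of that library, and RPM, reads per 1000000 counted reads, are given for that reason. Over miRNAs the factor was 0.683 in knockdown replicate 2. The same fits were tested on simulated data drawn from the real means, library sizes and spread. They recovered 58.3% of 4-fold changes among miRNAs, 58.3% among transposon families, 7.41% among loci and 0% among sequences. With a biological coefficient of variation of 0.2 in place of the fitted 0.411, 0.389, 0.778 and 0.847, in the same order, the same test recovered 79.8%, 92.7%, 100% and 52.1%.

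The 10 miRNA lists, of 65 miRNAs, covered the let-7 family, spermatocytes, the miR-17-92 proliferation clusters, the X-linked testis cluster, testis somatic cells, blood, spermatogonia, muscle and liver, the miR-182 group and epithelial miRNAs. Lists with at least 3 tested members, 9 in all, were tested with limma's camera at a preset correlation of 0.01 and with an estimated one, and with fry. The lists, the tests, the named-feature rule and the first set of alternatives below were fixed before the data were examined. The rule named the 5 most abundant miRNAs and sequences and the 10 most abundant loci, members of the miRNA lists, and the largest changes past the threshold. Where nothing passed, it took the 3 features of lowest p in each direction. Other named features are said to be chosen after their values were seen.

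Alternatives set before the data were examined were DESeq2, total library size, 21 to 23 nt reads as the scale of the loci, other filters, lengths and bases of the shares, distinct sequences counted once, 1 mismatch allowed, the replicate number as a block, and leaving out each library in turn. Added after the table was seen were mature miRNA reads as scale, 21 to 23 nt reads as the scale of the other tables, hairpin reads added to the mature miRNA, names as deposited, reads with 1 place in the genome, and all alternatives for the transposon families, the loci nearly without reads in knockdown replicate 1 and the tRNA-Gly fragments. In the fits with a library left out the lone library of a group is assumed to vary like the other group. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Features under the count filter were left out of the tests.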

Results

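Small RNAs were sequenced from whole testes of 16-day-old mice, 2 wild-type libraries and 2 libraries in which Hsf5 was knocked down per the labels. Hsf5 encodes heat shock factor 5, a testis transcription factor whose loss arrests spermatocytes in the pachytene stage of meiosis. At 16 days after birth the most advanced germ cells of the first wave of spermatogenesis are pachytene spermatocytes, the cells that begin to transcribe pachytene piRNA loci. These are long single-stranded RNA sources, most of them long non-coding genes, that are cut into piRNAs of about 25 to 31 nt. Shorter piRNAs of 25 to 28 nt are bound mainly by MILI, and longer ones of 29 to 31 nt by MIWI, 2 proteins of the PIWI family. The stated purpose of the series was to find piRNA changes, and its title names LINE1 retrotransposons, which piRNAs repress. The labels call the libraries biological replicates and do not say whether replicates of equal number shared a litter or a day. The libraries held 11117460 and 9260452 counted reads in wild type replicates 1 and 2, and 9619666 and 10900306 in knockdown replicates 1 and 2. Of these, 5745703, 5326809, 4352106 and 7025053 reads, in the same order, were 25 to 31 nt long. Levels of piRNA loci are given as RPM, reads per 1000000 counted reads of the library, and those of miRNAs, transposon families and sequences as CPM, counts per 1000000 reads of the same kind after TMM scaling. All values per library below follow that order, and errors are SDs over 2 libraries unless called SE. An exact two-sided permutation test of 2 against 2 libraries has 6 assignments and cannot give a p below 0.333.

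Hsf5 itself gave few reads in these libraries, which hold small RNAs and not the messenger RNA. Sense-strand exons of Hsf5 (GRCm39 chromosome 11, 87507946 to 87550368, plus strand) took 40 and 25 reads in the wild type and 21 and 24 reads in the knockdown. These came from 3920937, 3972016, 3144553 and 5226520 reads with 1 place in the genome. Fragments of this kind do not measure the level of the mRNA, so the degree of knockdown in either animal was not checked by these data.

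The size profile of the small RNAs differed more within the knockdown group than between the groups. Reads of piRNA length made up 53.3% and 59.7% of the reads in the wild type (56.5% ± 4.53) and 48.5% and 64.9% in the knockdown (56.7% ± 11.6; exact permutation p = 1). In the knockdown pair the spread came from the longer piRNAs. Reads of 29 to 31 nt took 17.6% and 19.0% in the wild type, 8.83% in knockdown replicate 1 and 24.4% in knockdown replicate 2, so the knockdown libraries lay on both sides of the wild type. Reads of 25 to 28 nt took 35.7%, 40.7%, 39.6% and 40.5%, and most of the smaller spread of the wild type lay there. With each distinct sequence counted once, reads of 25 to 28 nt took 45.9% and 46.9% in the wild type and 51.1% and 48% in the knockdown, higher in both knockdown libraries (exact permutation p = 0.333). The ratio of long to short piRNAs was 0.492 and 0.466 in the wild type (0.479 ± 0.0183) against 0.223 and 0.602 in the knockdown (0.412 ± 0.268). Reads of miRNA length, 21 to 23 nt, took 28.9% and 24.8% (26.8% ± 2.89) against 33.1% and 23.2% (28.2% ± 7.0). Wilson 95% intervals of the piRNA-length share reach at most 0.0327 points to either side, and like all intervals and floors here they cover counting error only, since PCR copies are not independent molecules. Without knockdown replicate 1 the difference in piRNA-length share was 8.41 points, and without knockdown replicate 2 it was -8.02 points.

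**Figure D1:**
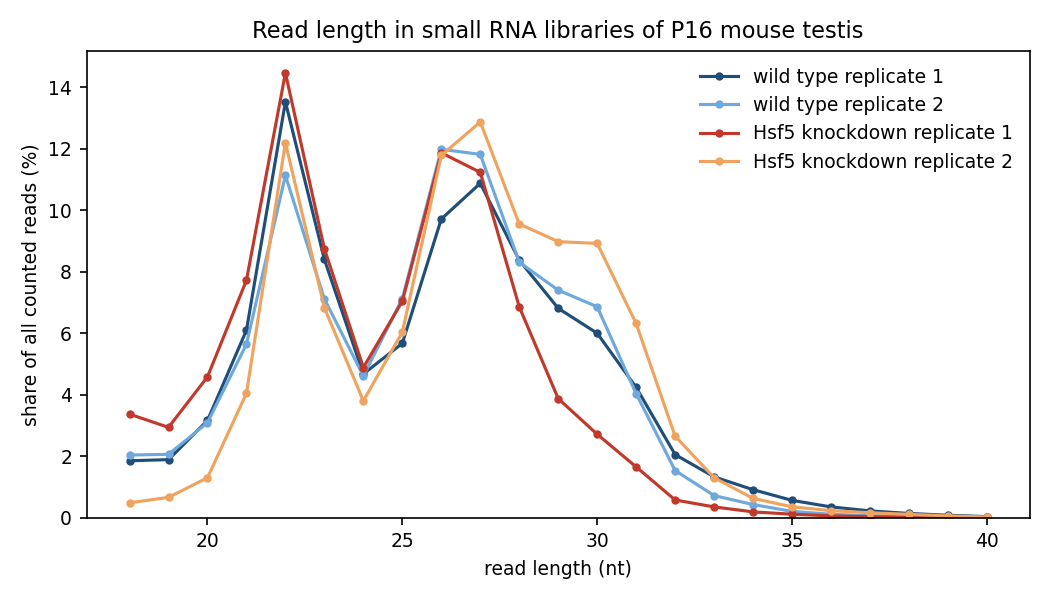
Share of counted reads (percent, vertical axis) at each read length (nt, horizontal axis), with 1 line for each of the 4 libraries. At 30 nt the share is 6.0% and 6.86% in the wild type, 2.72% in knockdown replicate 1 and 8.92% in knockdown replicate 2.

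The classes of the deposited annotation showed the same spread. piRNA clusters took 24.6% and 34.2% of all reads in the wild type (29.4% ± 6.82) and 25.1% and 38% in the knockdown (31.5% ± 9.10; exact permutation p = 0.667). miRNAs took 20.2%, 16.7%, 22.4% and 18.9%. Long terminal repeat elements took 11.6%, 12.8%, 12.8% and 11.5%, and LINE elements 5.70%, 6.30%, 6.73% and 4.91%. SINE elements took 8.07% and 8.23% in the wild type, 10.9% in knockdown replicate 1 and 6.0% in knockdown replicate 2. Among the reads of this class are short fragments with the sequence of the 5' end of large-subunit ribosomal RNA, such as CGCGACCTCAGATCAGA at 11663, 11690, 29492 and 931 CPM, so the share does not measure SINE RNA alone. The non-coding RNA class, which holds tRNA and similar fragments, took 15.9% and 9.94% against 12.5% and 6.96%. Reads of piRNA loci named after a host gene took 2.55%, 2.04%, 1.89% and 2.63% of the 25 to 31 nt reads. In none of the classes did both knockdown libraries lie on the same side of both wild-type libraries.

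Reads of piRNA length mostly began with U in all 4 libraries. Where reads of opposite strands overlapped, a 5' overlap of 10 nt was in excess over other lengths in each library. A 5' U, the first base of primary piRNAs, was on 76.4% and 83.6% of the 25 to 31 nt reads in the wild type (80% ± 5.09) and on 81.7% and 85.2% in the knockdown (83.5% ± 2.48; exact permutation p = 0.667). An A at base 10, the mark of piRNAs made by the ping-pong cycle, was on 25.7%, 26.7%, 24.5% and 25.8%. These shares are close to the 25% that equal use of the 4 bases would give. Among reads that do not start with U it was on 25.7% and 29.7% in the wild type and 23.8% and 25.1% in the knockdown. There both knockdown libraries lay below both wild-type libraries, which was not so over all reads. In the ping-pong cycle, piRNAs of opposite strands overlap by 10 nt at their 5' ends. The Z score of the ping-pong overlap over the genome was 40.8 and 42.8 in the wild type (41.8 ± 1.41), 50.1 in knockdown replicate 1 and 32.8 in knockdown replicate 2 (41.4 ± 12.2; exact permutation p = 1). Without knockdown replicate 1 its difference was -9.08 and without knockdown replicate 2 it was 8.22. With each distinct sequence counted once, both knockdown libraries lay below both wild-type libraries, with a Z score of 16.7 and 16.4 against 16.2 and 13.4 and a share of 10 nt among overlaps of 1 to 20 nt of 14.5% and 15.2% against 13.5% and 14.2%, each at the smallest exact p possible, 0.333.

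The share of piRNAs that match LINE1 did not separate the genotypes, and the measures of their ping-pong overlap disagreed. Reads of the LINE1 class were 3.22% and 3.26% of the 25 to 31 nt reads in the wild type (3.24% ± 0.0226) and 2.93% and 3.3% in the knockdown (3.12% ± 0.263; exact permutation p = 1). Reads in sense to 3542 full-length LINE1 elements found in GRCm39 took 0.232%, 0.140%, 0.127% and 0.198%, and antisense reads, the ones able to pair with LINE1 transcripts, 0.172%, 0.10%, 0.0883% and 0.127%, each with an exact permutation p of 0.667. The Z score of the ping-pong overlap in LINE1 elements was 11.1 and 7.97 in the wild type and 7.72 in each knockdown library, a difference of -1.84 that was -0.255 without wild type replicate 1. With each distinct sequence counted once it was 5.89 and 5.35 in the wild type and 3.83 and 3.45 in the knockdown. By the Z score both knockdown libraries lay below both wild-type libraries by either count, which chance gives in 1 direction or the other at the smallest exact p possible, 0.333. The share of overlaps of 10 nt among those of 1 to 20 nt did not separate the groups, at 41.5% and 26.1% in the wild type and 29% and 28% in the knockdown by reads, and 11.9% and 12.2% against 12.5% and 10.8% by distinct sequences. Of 25 families whose names begin with L1Md, 3 were higher and 22 lower in the knockdown, with a median log2 difference of -0.19. L1MdGf_II, chosen after its values were seen, had 6395 and 2883 CPM in the wild type and 2919 and 1835 in the knockdown (log2 difference -0.96, SE 0.44, between -1.42 and -0.29 with 1 library left out; adjusted p = 0.996, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Over all 145 L1 families the median was -0.03, with 66 higher and 79 lower.

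Across 793 transposon families, a test added after the table was seen, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 families. At an unadjusted p under 0.05 there were 10 higher and 6 lower, and DESeq2 also called 0. The family with the clearest difference was ID4_v, a tRNA-derived SINE, also chosen after its values were seen. It had 8137 and 4624 CPM in the wild type (6380.4 ± 2484) and 16474 and 19259 in the knockdown (17866 ± 1969), a log2 difference of 1.49 with an SE of 0.37 and an adjusted p of 0.996 by the same edgeR test. With the replicate number as a block, ID4_v was the 1 family called. Of its 60795 reads, 88.4% held the sequence of a tRNA-Gly fragment, and among reads with 1 place in the genome the log2 difference was -0.07. Without knockdown replicate 1 the edgeR test called 4 families higher and 4 lower, and without knockdown replicate 2 it called 12 higher and 41 lower.

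The abundant piRNA loci were expressed in both genotypes, with 2 exceptions in knockdown replicate 1. The strongest locus, 17-qA3.3-26735 (chromosome 17, 27544171 to 27586457, plus strand, 60.4% of its reads in the long non-coding gene Gm10505), took 58105 and 56769 RPM in the wild type (57437 ± 945) and 81781 and 58498 in the knockdown (70139 ± 16464). Its divergent neighbour 17-qA3.3-27363 (27507250 to 27544002, minus strand, 37.4% in Gm49793 and 58.7% intergenic) took 31106 ± 1606 against 38638 ± 8638. The intergenic locus 2-qE1-35981 (chromosome 2, 92371487 to 92439489, plus strand) took 14474 ± 5382 against 19119.5 ± 3522. The Gm52992 locus 14-qA3-19970 (chromosome 14, 24132062 to 24180159, plus strand) took 13195 ± 4054 against 18148 ± 4311, and the Gm30936 locus 9-qC-31469 (chromosome 9, 67598534 to 67641068, minus strand) 13486 ± 5070.0 against 17125 ± 4634. The remaining strong loci were 10-qC1-12816 (chromosome 10, 75673358 to 75700004, plus strand) at 5262 ± 2032 against 6864 ± 1895, 15-qD3-14639 (chromosome 15, 74508237 to 74530760, plus strand) at 7215 ± 2273 against 7755 ± 1907, and 15-qD1-17920 (chromosome 15, 59119215 to 59147071, minus strand) at 4538 ± 1725 against 5063 ± 2007. The log2 differences of these 8 loci lay between 0.43 (SE 0.55) and 0.83 (SE 0.82), with an adjusted p of 0.988 each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. They come from the fit after TMM scaling, with a factor of 0.661 in knockdown replicate 1, and are larger than the changes of the mean RPM shown. At 15-qD3-14639, for example, the fit gave a log2 difference of 0.45 where the mean RPM were 7215 and 7755. Scaled by mature miRNA reads instead, 15-qD3-14639 had -0.07 and 15-qD1-17920 had -0.01, and without knockdown replicate 1 the values of 17-qA3.3-26735 (-0.64), 17-qA3.3-27363 (-0.59), 2-qE1-35981 (-0.019), 15-qD3-14639 (-0.27) and 15-qD1-17920 (-0.082) were negative. Those of the last pair were also negative without wild type replicate 1, at -0.18 and -0.22. The other 3 stayed positive but came close to 0 with 1 library left out, at 0.074 for 14-qA3-19970, 0.00043 for 9-qC-31469 and 0.033 for 10-qC1-12816.

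The exceptions were 7-qD2-24830 and 5-qG3-23659, which were nearly silent in knockdown replicate 1 alone. The locus 7-qD2-24830 (chromosome 7, 73423665 to 73466217, minus strand, 97.6% of its reads in the long non-coding gene Gm10619) took 6629.8 and 11314 RPM in the wild type, 2.08 in knockdown replicate 1 and 10462 in knockdown replicate 2. The locus 5-qG3-23659 (chromosome 5, 149713537 to 149755054, minus strand, 86.0% in Gm21221) took 5603, 9846, 79.4 and 10719. The other loci with this profile that are named here were chosen after their values were seen. The divergent partner of the first, 7-qD2-11976 (chromosome 7, 73466343 to 73488642, plus strand, 97.7% in Gm21269), took 2759.6, 4691, 0.416 and 3987 RPM. The locus 5-qF-14224 (chromosome 5, 113488004 to 113524740, plus strand, 29.1% in 1700016C19Rik) took 4438, 7324, 1.56 and 6464. Inside introns of the aromatase gene Cyp19a1, 9-qA5.3-24188 (chromosome 9, 54114458 to 54157107, minus strand) took 1603, 3411, 0.208 and 2181. The coding gene locus pi-1700006A11Rik (chromosome 3, 124191732 to 124219640, minus strand, 85.8% in coding sequence) took 475, 723, 7.69 and 721.

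In all, 25 of the 214 loci had a CPM, after TMM scaling, in knockdown replicate 1 below 5% of the lowest other library, and 28 had an RPM below that limit, among them all 25. Of the 25 loci, on 12 chromosomes, 24 are named by chromosome band and 1 after a gene. Measured against the lower wild-type library alone, the same numbers of loci, 25 by CPM and 28 by RPM, were below 5% in knockdown replicate 1, and 0 of the 214 were in knockdown replicate 2 on either scale. These limits were chosen after the values were seen. Together the 25 took 8.47% and 13.6% of the 25 to 31 nt reads in the wild type, 0.0482% in knockdown replicate 1 and 12.1% in knockdown replicate 2. The other 76 loci named by band took 172436 and 230095 RPM in the wild type and 226214 and 261314 in the knockdown. In knockdown replicate 1 the 17-qA3.3 pair gave 81781 and 44746 of these RPM. Per mature miRNA read, the median log2 of the 76 in that library against the others was -1.23 (quartiles -2.45 and -0.60). On that scale 26 of the 76 were at or above the lowest other library, and loci named after a gene had a median of -0.92. Log CPM over the 214 loci correlated at 0.992 between knockdown replicate 2 and wild type replicate 2, at 0.967 between the wild-type libraries and at 0.462 between the knockdown libraries. These correlations are across loci, which are not independent replicates.

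**Figure D2:**
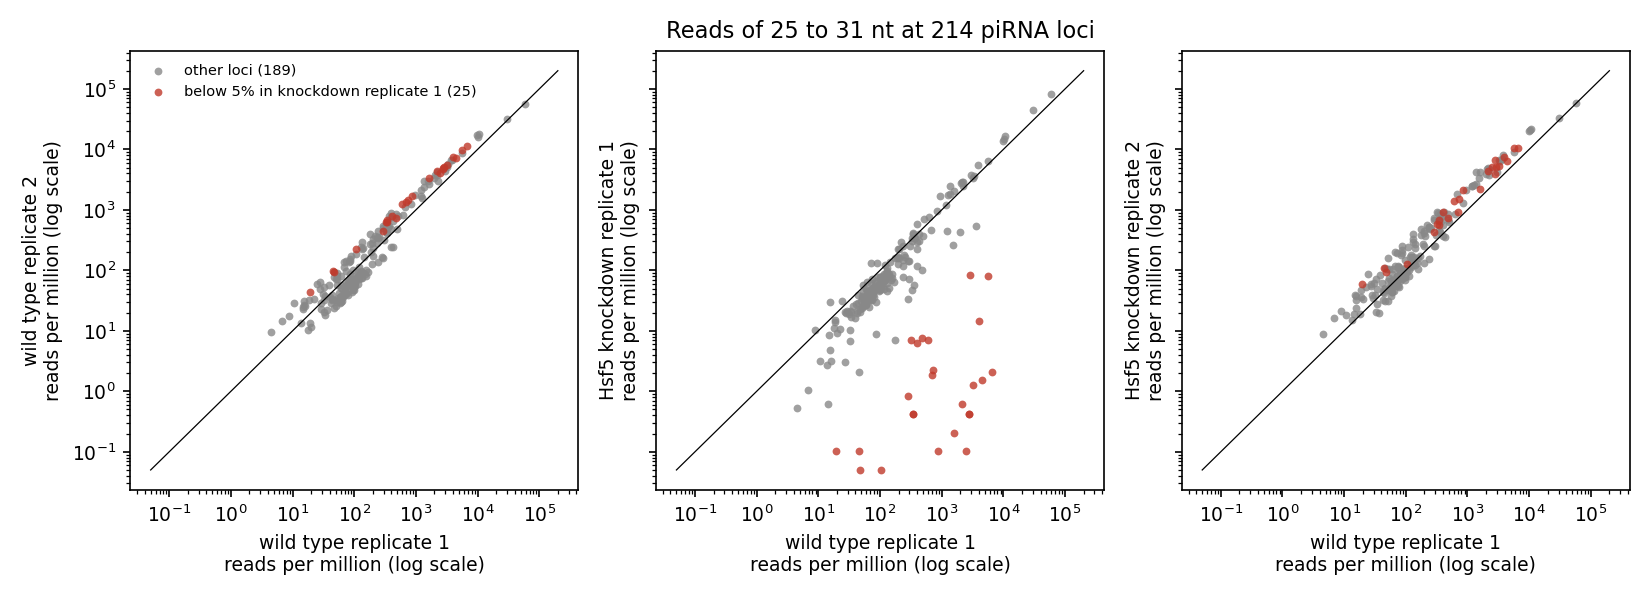
RPM (logarithmic axes, values under 0.05 drawn at 0.05) at the 214 piRNA loci in wild type replicate 2, knockdown replicate 1 and knockdown replicate 2, each against wild type replicate 1, with the diagonal as a line. The 25 loci in red fall far below the diagonal in knockdown replicate 1 and lie near it in the other panels.

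edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of the 214 loci between the genotypes, with 0 at an unadjusted p under 0.05, and DESeq2 called 0. The 3 lowest unadjusted p values belonged to small loci, and the next to the larger locus 10-qB4-6488. Named here are the 3 loci of lowest p in each direction. Their direction and log2 differences come from the fit after TMM scaling and not from the RPM shown. By RPM, knockdown replicate 1 lay below wild type replicate 2 at 14-qA3-284 (130 against 140) and at 10-qC1-117 (133 against 170). At 17-qC-59 both knockdown libraries lay above both wild-type libraries by RPM too. Higher in the knockdown were 17-qC-59 (AY702103, chromosome 17, 50544687 to 50554569; 20.8 ± 7.82 against 33.7 ± 6.12 RPM; log2 difference 1.08, SE 0.65), 14-qA3-284 (Gm41109, chromosome 14, 24462885 to 24479893; 106 ± 47.8 against 161 ± 42.6; 0.95, SE 0.58) and 10-qC1-117 (4930463O16Rik, chromosome 10, 84324158 to 84340701; 129 ± 58.2 against 194 ± 85.9; 0.85, SE 0.52). Lower were pi-Wdfy3, from the 3' UTR and coding exons of an autophagy scaffold gene (chromosome 5, 101980826 to 102217798; 46.2, 76.5, 2.08 and 50.3 RPM; -1.55, SE 1.09), pi-Cdc42ep3 (chromosome 17, 79641158 to 79662319; 19.7 ± 12.8 against 10.8 ± 10.8; -0.89, SE 0.77) and pi-Ipmk (chromosome 10, 71180743 to 71221711, 73.9% in the 3' UTR; 23.1 ± 10.9 against 14.3 ± 13.4; -0.72, SE 0.67). With 1 library left out the log2 differences of these 6 kept their direction but ranged from 0.27 to 1.52 for 17-qC-59, 0.20 to 1.33 for 14-qA3-284, 0.14 to 1.09 for 10-qC1-117, -3.86 to -0.89 for pi-Wdfy3, -1.63 to -0.35 for pi-Cdc42ep3 and -1.32 to -0.46 for pi-Ipmk. Without knockdown replicate 2 the edgeR test called 20 loci higher and 39 lower, and without knockdown replicate 1 it called 0. On simulated loci with the spread of these libraries, 4-fold changes were recovered in 7.41% and 16-fold changes in 42.3% of cases, so at this spread most 4-fold changes and many 16-fold changes shared by both animals would be missed.

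Among 936 miRNAs, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with 6 higher and 7 lower at an unadjusted p under 0.05, and DESeq2 called 1. That miRNA was miR-7686-5p, with 44.1 and 19.5 CPM in the wild type (31.8 ± 17.5) and 2.43 and 2.14 in the knockdown (2.28 ± 0.205). It rests on 110, 34, 6 and 3 reads, and its log2 difference was -3.76 with an SE of 0.69 and an adjusted p of 0.994 in edgeR. mir-7224 had 8, 6, 0 and 0 reads and mir-32 had 7, 5, 0 and 0, where 0 reads allow up to 3. Higher in the knockdown by the lowest unadjusted p were mir-142b (2, 1, 10 and 8 reads), mir-7210 (3.04 ± 0.246 against 11.9 ± 5.37 CPM) and miR-184-3p (191, 144, 254 and 743 CPM; log2 difference 1.57, SE 0.56, between 0.62 and 2.14 with 1 library left out). Without knockdown replicate 1 the edgeR test called 74 miRNAs higher and 49 lower, and without knockdown replicate 2 it called 2 higher and 0 lower.

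The most abundant miRNAs were those of the testis cluster on the X chromosome and a few of general expression. miR-881-3p, of the X cluster, had 62747 and 44837 CPM in the wild type and 38441 and 114231 in the knockdown (log2 difference 0.50, SE 0.66), and miR-470-5p, of the same cluster, had 53091 ± 3373 against 73848 ± 26639 (0.48, SE 0.52). miR-148a-3p had 45223, 39138, 33971 and 126620.0 (0.93, SE 0.71). miR-10b-5p had 35495 ± 2061 against 63656 ± 44566 (0.84, SE 0.64), and miR-99a-5p 43669, 50495, 51379 and 25891 (-0.29, SE 0.53). All 5 had an adjusted p of 0.994 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without knockdown replicate 2 the log2 difference was -0.46 for miR-881-3p, -0.29 for miR-148a-3p, -0.12 for miR-10b-5p and 0.16 for miR-99a-5p. Over the 24 miRNAs of at least 10000 CPM, the median log2 difference from the other libraries was -0.31, -0.39, -0.53 and 1.03, and over the 522 miRNAs of 10 to 10000 CPM it was -0.084, 0.0034, -0.042 and -0.059. The higher values of abundant miRNAs in knockdown replicate 2 depend in part on the TMM factor, 0.683 in that library and 1.12, 1.14 and 1.15 in the others, which raises all its CPM.

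None of the miRNA groups written down in advance passed between the genotypes, and 0 members of any tested list passed either adjusted over the list alone or over all miRNAs. All 9 tested members of the let-7 family, which accumulates with differentiation, were higher in the knockdown (median log2 difference 0.25; let-7c-5p 17324 ± 612 against 28052 ± 16791 CPM), with a camera adjusted p of 0.344 over the lists and 0.992 with an estimated correlation. With an estimated correlation camera has only the few residual degrees of freedom of these libraries. Its high p values, here and below, therefore do not show that correlation among members removed a signal. Without knockdown replicate 1 the estimated correlation of the let-7 list was negative, at -0.11. All 4 tested members of the epithelial miR-200 group were higher as well (median 0.54; miR-200a-3p 864 ± 73.9 against 1195 ± 325; camera adjusted p = 0.344, and 0.992 with an estimated correlation). That group rested on knockdown replicate 1 for miR-200c-3p, at 99.1, 92.2, 438 and 34.9 CPM. Without knockdown replicate 1 the let-7 list had a camera adjusted p of 0.00517 (0.979 with an estimated correlation), and without knockdown replicate 2 the epithelial list had 1.64e-05 (0.792 with an estimated correlation). The miR-182 group had 2 members higher and 1 lower (median 0.89; miR-182-5p 806 ± 142 against 1496 ± 1259.7). Without knockdown replicate 2 let-7c-5p and miR-182-5p had log2 differences of -0.070 and -0.39, and without knockdown replicate 1 miR-200c-3p had -1.46. The let-7 list as a whole also turned without knockdown replicate 2, with 3 members higher and 6 lower (median -0.043). Scaled by total library size it had 7 higher and 2 lower (median 0.056).

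The X-linked testis cluster had 4 members higher and 7 lower (median -0.13, mean 0.02; miR-471-5p 525 ± 9.78 against 354 ± 226). The miR-17-92 proliferation clusters had 3 higher and 6 lower (median -0.05), and miRNAs of spermatogonia 3 higher and 4 lower (median -0.19). Markers of other cell types a testis holds moved both ways. The somatic list had 3 higher and 3 lower (median -0.10, mean 0.07), with miR-202-5p of Sertoli cells at 2286 ± 279.7 against 1809.9 ± 498, miR-143-3p and miR-145a-5p of smooth muscle at 25653 ± 2922 against 39874 ± 20516 and 7545 ± 1685 against 5703 ± 78.8, and endothelial miR-126a-3p at 3625 ± 168 against 2631 ± 840.3. Blood miRNAs had 3 higher and 2 lower (median 0.13), and muscle and liver miRNAs 2 higher and 2 lower (median 0.23). Each of these lists, the miR-182 group included, had a camera adjusted p of 0.991 and of 0.992 with an estimated correlation. With limma's fry, which tests whether the members of a list move on balance 1 way, the lowest adjusted p of the 9 lists was 0.910. Of the 4 miRNAs of spermatocytes, 2 were tested, too few for a list test. miR-34c-5p had 3717, 6096, 4693 and 9226 CPM and miR-449a-5p, whose direction flips with scaling by mature miRNA reads (log2 difference 0.20, then -0.01), had 53.8, 112, 122 and 68.4. Their log2 differences also turned when 1 library was left out, to -0.028 for miR-34c-5p without knockdown replicate 2 and to -0.27 and -0.17 for miR-449a-5p without knockdown replicate 1 and wild type replicate 1.

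At the level of single sequences, 127017 were tested, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with 63 higher and 717 lower at an unadjusted p under 0.05, and DESeq2 called 0. The most abundant were the mature miRNAs miR-470-5p (TTCTTGGACTGGCACTGGTGAGT, chromosome X, 65857601 to 65857623, minus strand; 14662 ± 5074 against 16704 ± 2395 CPM), miR-881-3p (AACTGTGTCTTTTCTGAATAGA, chromosome X, 65845560 to 65845581; 15259 ± 7693 against 15721 ± 4247) and miR-148a-3p (TCAGTGCACTACAGAACTTTGT, chromosome 6, 51246809 to 51246830; 12352 ± 4577 against 16909 ± 6904). Next came a pair of short fragments that the deposited table puts in the SINE class that have no exact match in GRCm39 and that begin as large-subunit ribosomal RNA does. CGCGACCTCAGATCAGA had 11663, 11690, 29492 and 931 CPM and CGCGACCTCAGATCAGACGT had 12297, 9539, 18496.5 and 672. Leaving out 1 library turned the direction of each. It turned TTCTTGGACTGGCACTGGTGAGT (to -0.087 on the log2 scale) and AACTGTGTCTTTTCTGAATAGA (-0.34) without wild type replicate 2, TCAGTGCACTACAGAACTTTGT (-0.10) and CGCGACCTCAGATCAGACGT (0.69) without knockdown replicate 2, and CGCGACCTCAGATCAGA (-3.65) without knockdown replicate 1. Without knockdown replicate 2, AACTGTGTCTTTTCTGAATAGA also had -0.32. Without knockdown replicate 1 the edgeR test called 710 sequences higher and 8904 lower, and without knockdown replicate 2 it called 210 higher and 18119 lower.

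The lowest unadjusted p among sequences higher in the knockdown belonged to 2 fragments of the 5' end of tRNA-Gly and a similar sequence, led by GCATTGGTGGTTCAGTGGTAGAATTCTCGC at 527 and 394 CPM in the wild type and 5535 and 3284 in the knockdown (log2 difference 3.26, SE 0.58; adjusted p = 1.0, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). GCATTGGTGGTTCAGTGGTAGAATTCTCG had 3.60 (SE 0.67). The similar sequence, GCATTTGTGGTTCAGTGGTAGAATTCTCGC, which has no exact match in GRCm39 and which the deposited table puts in the LINE class as Lx2, had 3.19 (SE 0.69). These values of single lengths mix level and length, since the 30 nt form was 7.0%, 11.6%, 35.9% and 12.7% of the 5' fragments of tRNA-Gly-GCC and the 31 nt form 62.7%, 60.6%, 38.2% and 53.8%. All lengths together had a fold of 3.94. Sequences lower in the knockdown had 0 or nearly 0 reads there. The 3 of lowest p have no exact match in GRCm39. Whether the RNA or only a non-reference version of it was missing was not tested. At 5-qG3-23659, such versions held by the wild-type libraries alone had reference counterparts with 141 reads in knockdown replicate 2 and 1 in knockdown replicate 1. TAAAACGATGACGCTTCTGAAAGAGGA, which matches chromosome 5 at 149740328 to 149740354 in the locus 5-qG3-23659 with 1 mismatch, had 12.3, 14.4, 0 and 0 CPM. TACCGAGTTCTATCTAACCTTTGACCTGAT had 6.28, 8.91, 0 and 0, and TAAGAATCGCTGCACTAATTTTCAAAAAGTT had 9.91, 11.5, 0.146 and 0. A count of 0 allows up to 0.437 CPM on this scale in knockdown replicate 1 and 0.372 in knockdown replicate 2.

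**Figure D3:**
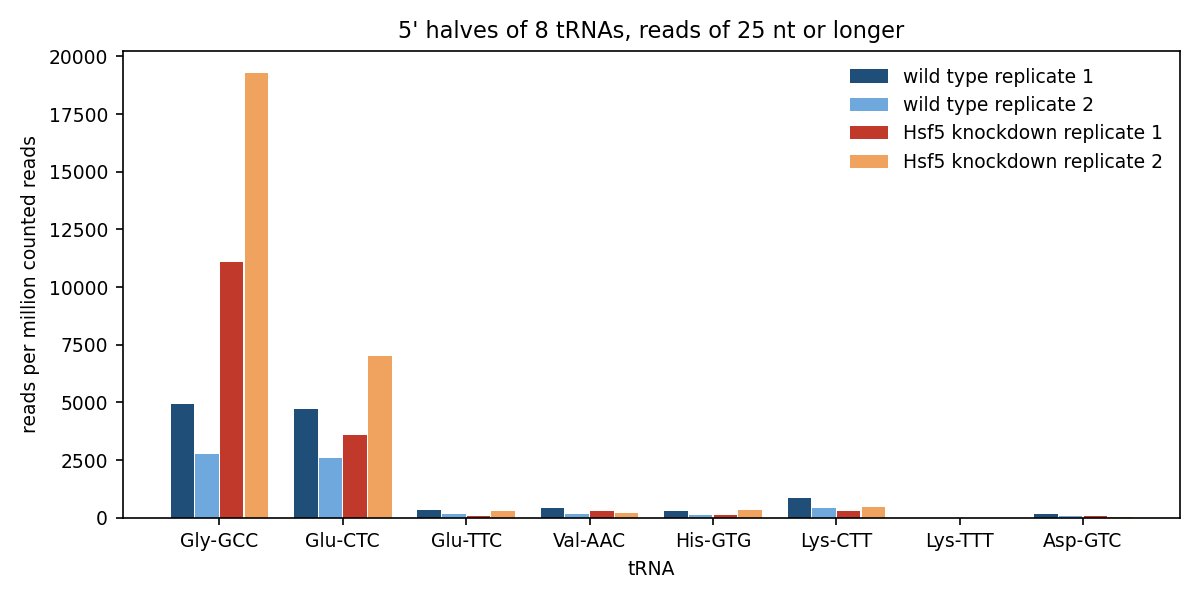
RPM (vertical axis) of 5' fragments of 8 tRNAs (horizontal axis), with 1 bar for each of the 4 libraries. For tRNA-Gly-GCC the wild-type bars stand at 4942 and 2761 and the knockdown bars at 11072.5 and 19277, while tRNA-Glu-CTC has 4702 and 2609 against 3591 and 7016.

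Some sequences at piRNA loci carried bases that differ from the reference, and the libraries differed in which version they held. Of the sequences with at least 10 reads in each of 2 libraries and 0 reads in the others, 163 shared by wild type replicate 1 and knockdown replicate 1 could be placed with 1 mismatch, all at the strongest pair of loci, 17-qA3.3 (chromosome 17, 27537911 to 27584879). Of the reads of these sequences and their reference versions together, 75.4% were non-reference in wild type replicate 1 (Wilson 95% interval 74.7% to 76.1%) and 77.3% in knockdown replicate 1 (76.6% to 77.9%), while wild type replicate 2 had 6556 and knockdown replicate 2 had 8050 reference reads. At 6-qF3 (chromosome 6, 127766397 to 127812157) 15 such sequences were shared by the wild-type libraries, and knockdown replicate 2 had 360 reads of the reference versions alone. Knockdown replicate 1 had 0 reads of either version there, so its version is not known. These regions were chosen after the sequences were seen, and the 0% in the libraries without the sequences follows from how they were chosen. The shares in the libraries that hold the sequences depend on that choice too. They and their intervals therefore do not estimate the share of a version over a whole locus.

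**Figure D4:**
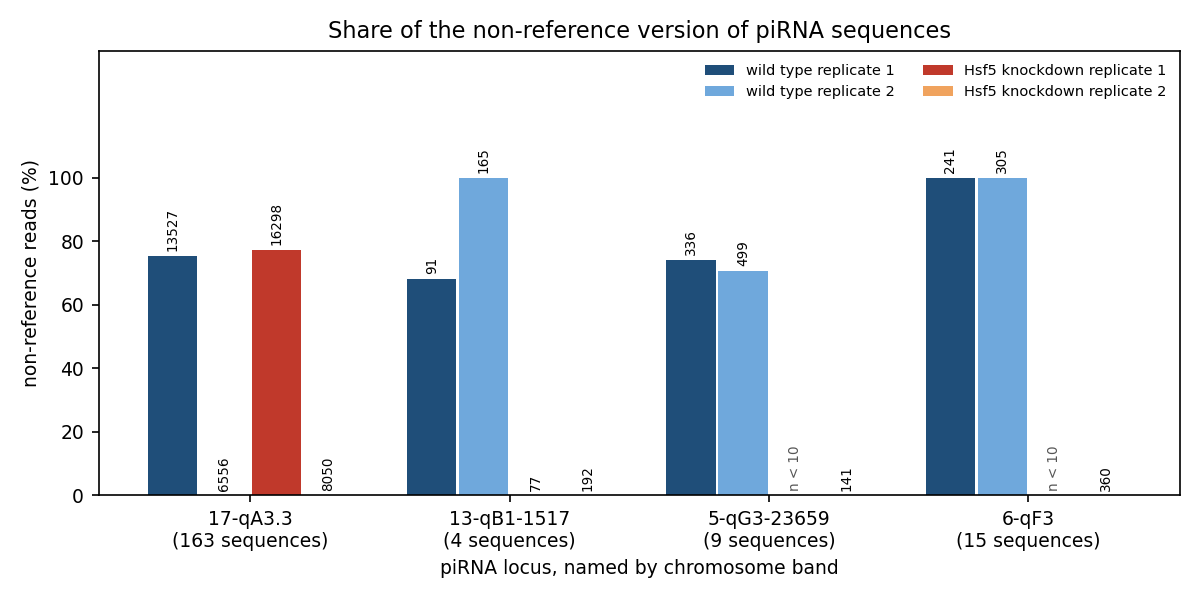
Share of non-reference reads (percent, vertical axis) among the reads of sequences placed with 1 mismatch and their reference versions, at 4 regions (horizontal axis), with 1 bar for each library that has at least 10 such reads and the number of reads above it. At 17-qA3.3 the share is 75.4% in wild type replicate 1 and 77.3% in knockdown replicate 1.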

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

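All tests in this part were chosen only after the result was seen. The 5' fragments of tRNA-Gly-GCC, outside the miRNA and piRNA comparisons, stood above the level of the control libraries in both knockdown libraries. Reads of at least 25 nt were assigned to a tRNA by their first 18 bases alone. Any other tRNA that shares these bases was not told apart. Such fragments, which end in the anticodon loop, are abundant in the male reproductive tract. They took 4942 and 2761 RPM in the wild type (3851 ± 1542) and 11072.5 and 19277 in the knockdown (15175 ± 5802), a fold of 3.94, or 3.67 per mature miRNA read. The lower knockdown library was 2.24 times the higher wild-type library. Without wild type replicate 1 the fold was 5.50, the highest of the 4 values with a library left out, and the lowest was 2.87. The SINE family ID4_v, whose reads are mostly this sequence, had 8137, 4624, 16474 and 19259 CPM.

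Longer inserts in the knockdown libraries are argued against by the 5' fragments of the other 7 tRNAs, of similar length, at 6808, 3567, 4456 and 8445 RPM, a fold of 1.24 that stayed between 0.859 and 1.81 with a library left out, below the 2.87 of tRNA-Gly-GCC. Most of these reads were of tRNA-Glu-CTC, at 4702, 2609, 3591 and 7016 RPM. Its fragments were most often 33 nt long, against 31 nt for tRNA-Gly-GCC. All reads of 29 to 31 nt took 17.6%, 19.0%, 8.83% and 24.4%, so only knockdown replicate 2 had more of them than the wild type. A general rise of non-coding RNA fragments of 28 to 33 nt is argued against by the other such reads, at 41568, 17853, 14458 and 15191 RPM. Their fold was 0.499, and 0.830 without wild type replicate 1. They do not settle whether the knockdown RNA was more degraded, since degradation also gives shorter fragments. Reads of 17 nt took 1.99% and 2.40% of all reads in the wild type, 4.41% in knockdown replicate 1 and 0.386% in knockdown replicate 2. An effect of the knockdown on these fragments, more degraded RNA or an unrecorded difference in how the testes were taken may be the source. The exact two-sided permutation p was 0.333, the smallest that 2 against 2 libraries can give. With 1 such quantity picked from many, chance cannot be told apart from any of these.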

How the results depend on the processing

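Libraries left out aside, the features called by any setting were 1 miRNA and 1 transposon family, each by 1 setting. With other settings, 519 of 526 values of 55 named features kept their direction and their side of the threshold, 2 passed it and 5 turned, and of 78 values of other results 69 kept both, 2 passed and 7 turned. Under DESeq2 1 of the miRNAs passed, miR-7686-5p. The piRNA-length share differed by -0.505 points with reads of 24 to 33 nt and by -0.0304 with each distinct sequence counted once. The LINE1-matching share of full-length elements in sense differed by 0.00579 with each distinct sequence counted once. With reads of 25 to 31 nt only, the annotation classes differed by -0.0169 points for miRNA, 0.150 for LTR, -0.0223 for SINE and 0.151 for others. Scaled by mature miRNA reads, a setting added after the table was seen, 15-qD3-14639 (piRNA loci) had a log2 difference of -0.074, 15-qD1-17920 (piRNA loci) -0.013 and mmu-miR-449a-5p (miRNAs) -0.0062. With reads of 1 place in the genome, also added then, ID4_v (transposon families) had -0.068. The cause was not tested, except that the last leaves out the tRNA-Gly reads, which have many places. The 50 kb windows were not run, since the table has its own loci.

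The labels tie libraries of equal replicate number by that number alone. Their deviations from the group means correlated at 0.31 over sequences, 0.0093 over miRNAs, 0.49 over loci and 0.25 over transposon families. With the replicate number as a block, 1 of the transposon families passed, ID4_v, higher in the knockdown, and CGCGACCTCAGATCAGA (small RNA sequences) had a log2 difference of -1.15. The block changed no other call, and counts of calls for sequences, miRNAs, piRNA loci and miRNA lists stayed at 0.

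Leaving out 1 library moved far more, and fits with a lone library assume that it varies like the other group. Of 208 values of named features 143 kept direction and side, 42 passed the threshold and 23 turned, and of 116 others 78 kept both, 9 passed, 28 turned and 1 moved. The number past the threshold ranged from 0 to 18329 for small RNA sequences, 0 to 123 for miRNAs, 0 to 59 for piRNA loci, 0 to 53 for transposon families and 0 to 1 for miRNA lists, each 0 without either wild-type library. In points, the piRNA-length share ranged from -8.02 to 8.41, its part of 25 to 28 nt from -0.632 to 4.37 and of 29 to 31 nt from -9.45 to 6.10, the miRNA-length share from -3.61 to 6.29 and the 5' U share from -0.113 to 7.08. The long to short piRNA ratio ranged from -0.256 to 0.122 and the ping-pong overlap from -9.08 to 8.22. The LINE1-matching share ranged from -0.311 to 0.0609, in full-length elements in sense from -0.0697 to 0.0222 and antisense from -0.0643 to 0.00727. Of the annotation classes, piRNAcluster ranged from -4.29 to 8.58, nrRNA from -0.209 to 0.0710, LINE from -1.09 to 0.731, LTR from -0.770 to 0.575, SINE from -2.15 to 2.74, genes from -2.28 to 0.378, tegRNA from -0.307 to 0.0229, others from -0.966 to 0.886 and genic piRNA loci from -0.402 to 0.340.

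With 1 library left out, log2 differences ranged as follows. Among small RNA sequences, TTCTTGGACTGGCACTGGTGAGT had -0.087 to 0.51, AACTGTGTCTTTTCTGAATAGA -0.34 to 0.63, TCAGTGCACTACAGAACTTTGT -0.10 to 0.86, CGCGACCTCAGATCAGA -3.65 to 1.26 and CGCGACCTCAGATCAGACGT -4.02 to 0.69. Among piRNA loci, 17-qA3.3-26735 had -0.64 to 1.46, 17-qA3.3-27363 -0.59 to 1.49, 2-qE1-35981 -0.019 to 1.22, 15-qD3-14639 -0.27 to 0.84 and 15-qD1-17920 -0.22 to 0.71. Among miRNAs, miR-881-3p had -0.46 to 1.08, miR-148a-3p -0.29 to 1.58, miR-10b-5p -0.12 to 1.42, miR-99a-5p -0.87 to 0.16, let-7c-5p -0.070 to 1.20, miR-34c-5p -0.028 to 0.90, miR-449a-5p -0.27 to 0.82, miR-182-5p -0.39 to 1.56 and miR-200c-3p -1.46 to 2.22. Others kept their direction but came near 0, such as miR-470-5p at 0.077 to 0.80, miR-471-5p at -1.45 to -0.0054, miR-143-3p at 0.014 to 1.08, miR-202-5p at -0.66 to -0.056 and miR-145a-5p at -0.62 to -0.095, and miR-126a-3p at -0.84 to -0.14, miR-200a-3p at 0.19 to 0.71 and L1MdGf_II (transposon families) at -1.42 to -0.29 moved too. For the piRNA loci the spread between libraries, rather than depth, set the limit, since simulated loci at a biological coefficient of variation of 0.2 were all recovered at the same depth. For miRNAs and sequences 79.8% and 52.1% of 4-fold changes were recovered at that spread, and what limited the rest was not tested.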

Other observations

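The tests of both patterns in this part were chosen only after the result was seen. Of the 25 piRNA loci nearly without reads in knockdown replicate 1, 16 belonged to divergent pairs, in which both loci were affected, and 9 had no such partner. Of 14 neighbouring pairs of loci that point away from each other within 1000 bp, as from a shared promoter, 8 had both loci nearly without reads, 6 had neither and 0 had 1 of the pair (exact Fisher p = 0.000333, which treats the pairs as independent). Such pairs lay for example at Gm10619 and Gm21269 on chromosome 7 and at 1700016C19Rik on chromosome 5. Of the pairs with neither locus under the limit, 6-qF3 was at 0.36 and 0.24 of the lowest other library in knockdown replicate 1. The pair at 7-qF3 was at 0.41 and 0.25, and the rest lay above the lowest other library. The division of the pairs therefore depends on the 5% limit, which was chosen after the values were seen. Reads that the deposited table put outside the loci showed the same gap. There, 39 genes of 21801 had under 5% of the lowest other library in knockdown replicate 1, 23 of them long non-coding, against 5, 13 and 15 genes in wild type replicates 1 and 2 and knockdown replicate 2. Several of the 39 are host genes of the same loci, so these reads are no separate evidence. Gm21269 had 4391, 6496, 0 and 6257 such reads, Gm50166 had 1614, 2572, 2 and 2390, and the coding genes Qrich2 and Morc2b had 43, 73, 0 and 43 and 48, 51, 0 and 68. Among 6 transposon families with this profile, LTR91 had 3420, 4346, 48.2 and 3598 CPM and MLT2F had 1834, 2994, 66.4 and 2805.

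Selection of shorter inserts as the whole source of this gap in knockdown replicate 1 is argued against by the shorter reads, since of 30 loci under the limit in reads of 29 to 31 nt, 25 were also under it in reads of 25 to 28 nt. An effect of the knockdown shared by both libraries is argued against by the loci chosen against the wild type alone, of which 0 were under the limit in knockdown replicate 2, where their log2 difference from the wild-type mean lay between -0.77 and 0.56. An earlier stage of spermatogenesis in that animal, which a pachytene arrest or a younger animal might give, stays open: the other loci named by band had a median log2 of -1.23 per mature miRNA read against the other libraries, but loci named after a gene had -0.92, 17-qA3.3 was higher there, and neither miR-34c-5p nor miR-449a-5p was below both wild-type libraries. A mislabelled library or a knockdown that differed in degree also stays open, since knockdown replicate 2 correlated at 0.992 over the loci with wild type replicate 2 and Hsf5 could not be measured, so these cannot be told apart with 1 such library. Over miRNAs the order was the other way. There knockdown replicate 1 correlated at 0.980 and 0.977 with wild type replicates 1 and 2, and knockdown replicate 2 at 0.955 and 0.953. The wild-type libraries correlated at 0.980 with each other. Knockdown replicate 2 stood apart from both wild-type libraries in the 5' fragments of tRNA-Gly-GCC, at 19277 RPM against 4942 and 2761, and at 6-qF3, with 0 of 360 non-reference reads against 100% in each, but both were picked after their values were seen, and a wild-type animal of another background would also differ at 6-qF3, so they do not settle it.

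Of 320 sequences with at least 10 reads in wild type replicate 1 and knockdown replicate 1 and 0 in the others, 93.1% had no exact match in GRCm39, against 8.24% of 27833 sequences held by all 4 libraries, which argues against sampling of scarce sequences. The libraries of replicate number 2 shared 112, of which 13.4% had no exact match, and the wild-type libraries shared 96, of which 55.2% had none. Of the sequences placed with 1 mismatch in the pairs of equal replicate number, 78.0% had their reference version in both libraries that lacked them, which is consistent with animals of differing genetic background at 17-qA3.3 on chromosome 17. Of 35 non-reference sequences on 8 chromosomes held by both wild-type libraries and neither knockdown library, 6 had their reference version in both knockdown libraries. At 13-qB1-1517, with 4 of the 35, non-reference reads were 68.1% and 100% in the wild type and 0 of 77 and 0 of 192 in the knockdown. At the other places knockdown replicate 1 had at most 1 read of either version, so its version there is not known. No source of such a difference in background was tested, and whether the backgrounds also bear on the gap in knockdown replicate 1 was not tested.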
